A study of Mus musculus with 4 samples.

How the data were processed

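The data are droplet single-cell RNA counts from the hippocampus of 13-month-old female APP/PS1 mice, a transgenic model that deposits amyloid in the brain. The mice carried intact Ptpn1 (PTP1B+/+) or lacked it (PTP1B-/-); Ptpn1 encodes the protein tyrosine phosphatase PTP1B. Per the labels, hippocampal tissue was dissociated in the presence of inhibitors of transcription and translation, viable cells were sorted, and 10x Genomics 3′ libraries were sequenced to a mean of about 50000 reads per cell. The labels describe 4 libraries in 2 groups of 2, and each library pools cells of 2 animals. PTP1B+/+ replicate 1 (15441 barcodes) was not analysed here, so 1 PTP1B+/+ library stands against 2 PTP1B-/- libraries.

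Per the labels and the values themselves, the authors deposited raw UMI counts per gene and barcode, as filtered matrices with no normalization. The submitters' processing notes name Cell Ranger 7.1.0, Seurat 5.1.0, and the builds mm10 and GRCm38, without saying which step used which tool. Cell calling settings, the handling of intronic reads and the handling of strand are not given in the sources used here. The matrices list 32285 genes. Gene positions were taken from a GENCODE annotation of GRCm38, in which 32235 of those gene identifiers were found.

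The total count was 120814371 UMIs in 13031 barcodes for PTP1B+/+ replicate 2, 45064948 UMIs in 6911 barcodes for PTP1B-/- replicate 1 and 29119752 UMIs in 4958 barcodes for PTP1B-/- replicate 2. Barcodes were kept with at least 300 genes, at least 500 UMIs and at most 10% of UMIs from mitochondrial genes. That removed 701, 797 and 562 barcodes in the same order. Scrublet, as run in scanpy 1.11.5 per library with an expected rate rising with the number of barcodes, called 506, 217 and 118 barcodes as doublets (3.88%, 3.14% and 2.38%, against expected rates of 10.4%, 5.53% and 3.97%), and these were removed. After both steps 11852, 5925 and 4290 cells were kept, with median UMI counts of 8270, 6578 and 5811.

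Kept cells were clustered together on log-normalised counts with 2000 variable genes chosen per library, 30 principal components, 15 neighbours and Leiden clustering at resolution 1, without batch integration. The 29 clusters were named from marker genes fixed before the data were examined. The naming thresholds were set afterwards: a marker counted as detected in at least 20% of a cluster's cells and at 20 CPM, a name needed 3 detected markers, and a class needed a median marker level of at least 0.25 of that marker's highest cluster. A cluster stayed unnamed when markers of another lineage reached 0.2 of their highest level, when its leading genes belonged to another class, or when its cells were shallow and lacked markers among its leading 10 genes. That left 7 clusters unnamed, and the remaining classes are called microglia-like, oligodendrocyte-like and so on, because they rest on markers alone. Shares of cells have exact Clopper-Pearson 95% intervals and single counts have exact Poisson 95% intervals. Both cover counting error only.

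Raw counts were summed per library over each class with at least 50 cells in every library, which gave 7 classes. Each was tested with edgeR 4.0.16 in R 4.3.3: TMM scaling, filterByExpr by group, robust dispersion, quasi-likelihood F test, and Benjamini-Hochberg adjustment over all genes tested, called at an adjusted p of 0.05. Libraries, not cells, are the replicates. The fit has 1 residual degree of freedom, the spread is borrowed across genes, and the lone PTP1B+/+ library is assumed to vary like the PTP1B-/- libraries. Levels given as TMM-scaled CPM come from this fit, and fold changes are PTP1B-/- over PTP1B+/+. Differences between cell classes were tested with a genotype-by-class interaction with library as a block. The share of T cell RNA in microglia-like sums was bounded by the upper exact limit of the summed UMIs of 11 T cell markers over their level in T cell-like cells, and set against the share each risen interferon or antigen presentation member would need. In a step chosen after the data were seen, the choroid plexus RNA in a PTP1B+/+ sum was taken as its Ttr CPM over that of choroid plexus-like cells, and the CPM this share would bring was set against the fall to the mean of both PTP1B-/- libraries.

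The 24 gene lists and the marker lists were fixed before the data were examined too, and were tested with camera in limma 3.58.1 at a preset correlation of 0.01, adjusted over all lists tested in a class. The same test with an estimated correlation and fry's directional test were run beside it. With an estimated correlation the test rests on the 1 residual degree of freedom, so it could hardly call any list. Its misses therefore do not count against a list, and it was not tried on the simulated data below. Members are counted as called over all genes, and also as adjusted over the list alone. The genes named in each comparison follow a fixed rule: Ptpn1; among called genes with a mean log2 CPM of at least 5 and both PTP1B-/- libraries on the same side, the 10 largest rises and 10 largest falls in microglia-like cells and 5 of each elsewhere, leaving out unnamed gene models, mitochondrial and ribosomal protein genes; for each list up to 2 called members per direction with the smallest p, or the 2 with the highest mean level; and in microglia-like cells always Syk, Trem2, Tyrobp, Apoe, Cst7, Clec7a, P2ry12 and Cx3cr1. Clec7a has no value in the fit, and some genes this rule picks are not reported here. Any other gene named was chosen after its values were seen.

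The tests were tried on simulated data drawn from the real means, library sizes and fitted dispersions. Genes were drawn independently and with no shift shared by a whole library, so the counts of false calls do not cover such shifts. For the microglia-like comparison (13994 genes) the fit called 19.4% of genes changed by 1.5-fold, 64.2% of those changed by 2-fold and 97.0% of those changed by 4-fold, with 5 unchanged genes called; with no gene changed it called 0 genes and 0 lists. The interaction of microglia-like and oligodendrocyte-like cells recovered 75% of simulated 4-fold differences. Alternatives were other size factors, no filter on low counts, the older quasi-likelihood fit, DESeq2 1.42.0, a 5% mitochondrial limit, keeping called doublets, thinning to 661 cells per library and 2000 UMIs per cell (leaving out 261, 86 and 51 shallower microglia-like cells), leaving out genes of other cell types, other clusterings, and leaving out single clusters or libraries.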

Results

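The measurements compare single cells of the hippocampus of 13-month-old female APP/PS1 mice with and without PTP1B, the phosphatase encoded by Ptpn1. The series title names microglial phagocytosis and SYK signalling, so the main question is how the microglial transcriptome differs between the genotypes. Of PTP1B+/+, replicate 2 was analysed (11852 kept cells), and of PTP1B-/-, replicates 1 and 2 (5925 and 4290 kept cells). Total counts after filtering were 108928282, 41199753 and 26907522 UMIs. Each library pools 2 animals, so the spread between libraries is that between pools.

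Ptpn1 (ENSMUSG00000027540, GRCm38 chromosome 2, 167932057 to 167979385) was far lower in both PTP1B-/- libraries. In microglia-like cells it measured 237 CPM (95% Poisson interval 231 to 244) in PTP1B+/+ replicate 2, and 28.2 CPM (25.1 to 31.5) and 29.1 CPM (24.3 to 34.4) in PTP1B-/- replicates 1 and 2, from 5679, 303 and 134 UMIs. The log2 fold change was -3.0 (SE 0.12, edgeR adjusted p = 8.68e-11). Over all kept cells Ptpn1 was at 90.6, 8.88 and 6.76 CPM. Border macrophage-like cells kept 30.1 and 16.7 CPM against 237 CPM, and T cell-like cells 13.8 and 10.7 CPM against 112 CPM. In oligodendrocyte-like cells the 2 PTP1B-/- libraries held 3 and 1 UMIs against 843, and in neuron-like cells 0 and 0 against 141, where the exact intervals of 0 UMIs reach up to 8.88 and 6.21 CPM. The labels do not name the allele, so 3′ reads may lie outside the deleted part and do not by themselves show how much functional transcript remained.

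**Figure D1:**
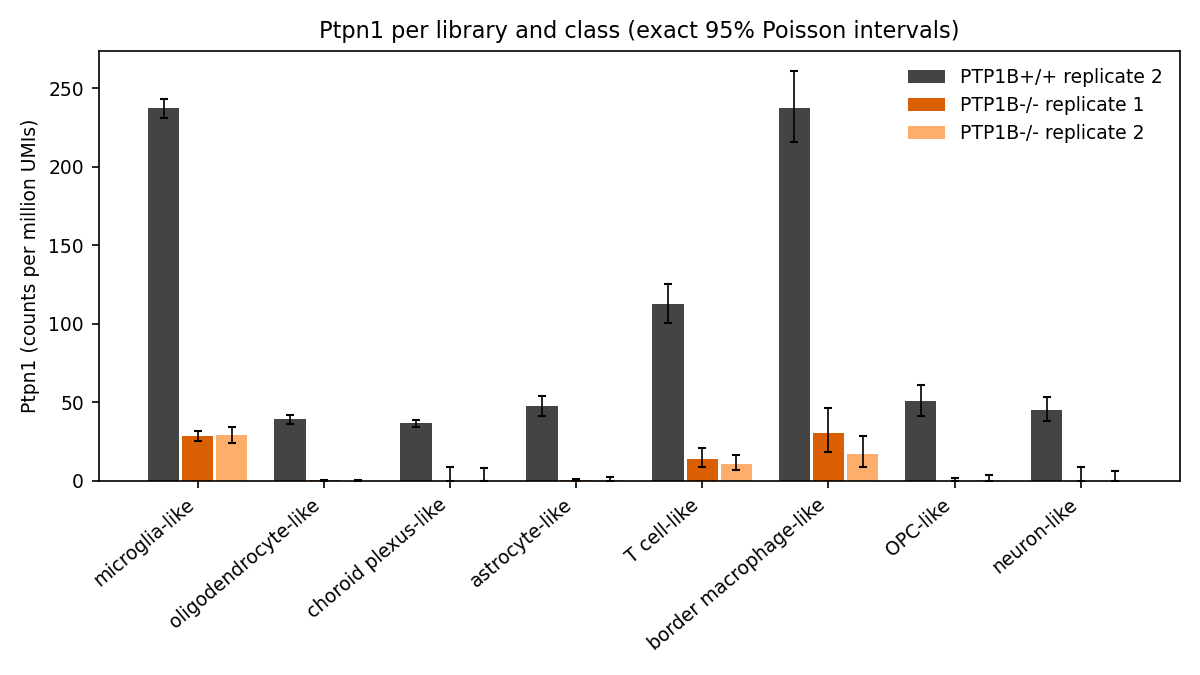
Ptpn1 in CPM (y axis, from 0) by cell class (x axis) for the PTP1B+/+ library and the 2 PTP1B-/- libraries; bars are the summed counts of a class and lines are exact 95% Poisson intervals. Microglia-like cells stand at 237 CPM against 28.2 and 29.1 CPM.

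The cell suspensions differed in composition. Choroid plexus-like cells, the epithelium that makes cerebrospinal fluid and transthyretin, were 5011 of 11852 cells in PTP1B+/+ replicate 2 (42.3%, interval 41.4 to 43.2), against 49 cells (0.827%, 0.612 to 1.09) and 63 cells (1.47%, 1.13 to 1.88) in the PTP1B-/- libraries. Oligodendrocyte-like cells made up 12.9%, 31.2% and 34.1%, astrocyte-like cells 4.24%, 12.5% and 11.7%, and microglia-like cells 23.2%, 25.2% and 16.6%. T cell-like cells were 2.90%, 4.41% and 8.69%, and oligodendrocyte precursor-like (OPC-like) cells 1.52%, 3.43% and 3.73%. With choroid plexus-like cells left out of the denominator, microglia-like cells were 40.3%, 25.4% and 16.8% of cells. These shares leave out cluster 22, unnamed shallow cells (median 1259 UMIs) closest to microglia, kept out by a threshold set after the data were seen, with 84, 465 and 386 cells (0.709%, 7.85% and 9.0%). Counting it as microglia would put both PTP1B-/- libraries above PTP1B+/+ in the share of all cells, and both still below it without choroid plexus-like cells. The oligodendrocyte-like shares likewise leave out unnamed cluster 10, closest to oligodendrocytes, with 203, 369 and 167 cells (1.71%, 6.23% and 3.89%). An exact permutation of 1 library against 2 cannot give a p below 0.333, so no share was called different.

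**Figure D2:**
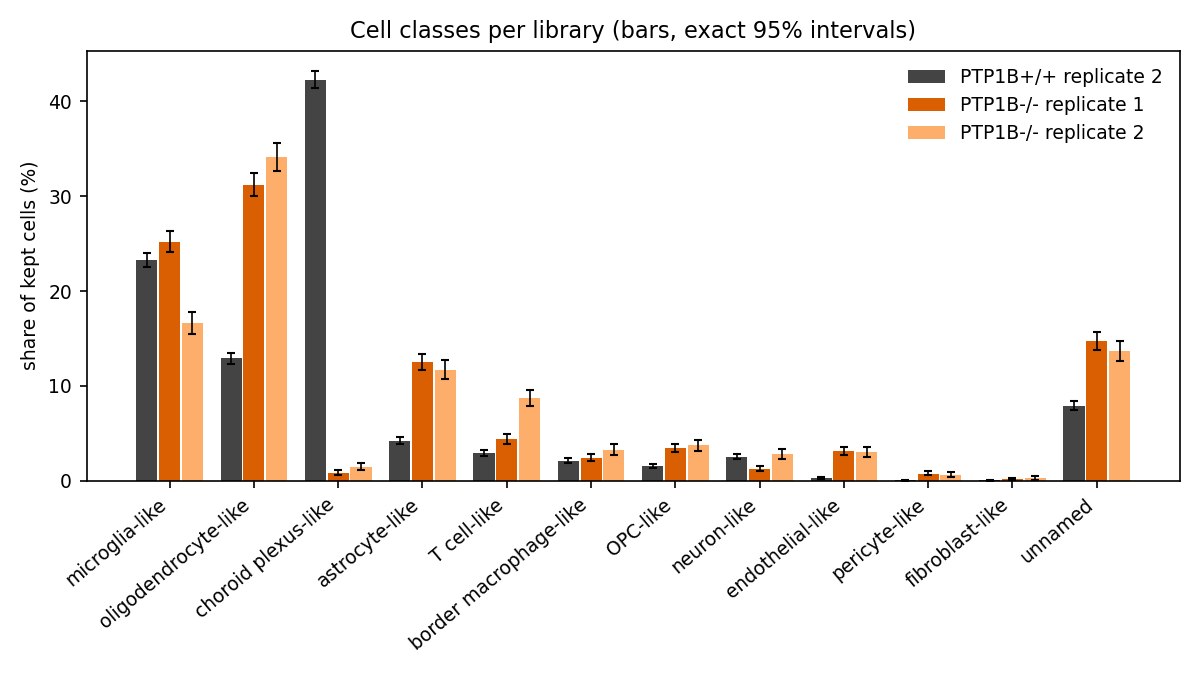
Share of kept cells in percent (y axis, from 0) by cell class (x axis) in each of the 3 libraries, with exact 95% binomial intervals. Choroid plexus-like cells fill 42.3% of the PTP1B+/+ library and 0.827% and 1.47% of the PTP1B-/- libraries.

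In microglia-like cells 425 genes were higher and 491 lower in PTP1B-/- of 13994 tested, and 915 of these 916 had both PTP1B-/- libraries on the same side of the PTP1B+/+ library. Among called genes with a mean log2 CPM of at least 5 and both PTP1B-/- libraries on the same side, the largest falls besides Ptpn1 were in Scoc (-3.15, SE 0.15; 134 CPM against 14.1 and 16.6 CPM), a short coiled-coil protein linked to autophagy, Magi1 (-2.57, SE 0.16), a scaffold protein of cell junctions, and Serinc3 (-2.39, SE 0.13; 1243 CPM against 216 and 259 CPM), a membrane protein encoded on chromosome 2 at 163623272 to 163645131. Slc15a2, a peptide transporter, fell too (-1.68, SE 0.28), with Rnf121 (-1.50), Hk2, a hexokinase of glycolysis (-1.35), Zfp729a (-1.33) and Atp5k (-1.30). Tsix also fell (-1.34); it is antisense to Xist, and without stated strand handling its reads cannot be told from those of its partner.

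Within the same limits, the largest rises were in Trim30d (3.05, SE 0.16; 15.1 CPM against 133 and 116 CPM), Trim12a (3.01, SE 0.15) and Trim5 (2.80, SE 0.20), which lie together on chromosome 7 between 104263386 and 104507849 and belong to a family of near-identical copies, so their reads may be shared. The chemokine genes Ccl12 (2.59, SE 0.14; 64.0 CPM against 363 and 411 CPM) and Ccl5 (2.34, SE 0.19) rose, as did Pianp (2.65, SE 0.27), Sox5 (2.35, SE 0.15), a transcription factor, and the interferon-induced Ifitm3 (1.97, SE 0.13) and Oasl2 (1.87, SE 0.15). H2-K1, a class I histocompatibility gene, rose by 2.08 (SE 0.20; 366 CPM against 1788 and 1312 CPM); H2-K1, H2-D1 and H2-T23 are similar in sequence, and their separate values are uncertain. With DESeq2 329 genes were called in place of 916, with 203 higher and 126 lower where the planned fit had more lower genes. Of these, 310 were shared with the edgeR calls, all with the same sign. Leaving out cluster 11, which held the largest part of the PTP1B+/+ microglia-like cells (1217 of 2755) while cluster 14 held the largest part in both PTP1B-/- libraries (615 of 1494 and 329 of 712), gave 358 genes.

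**Figure D3:**
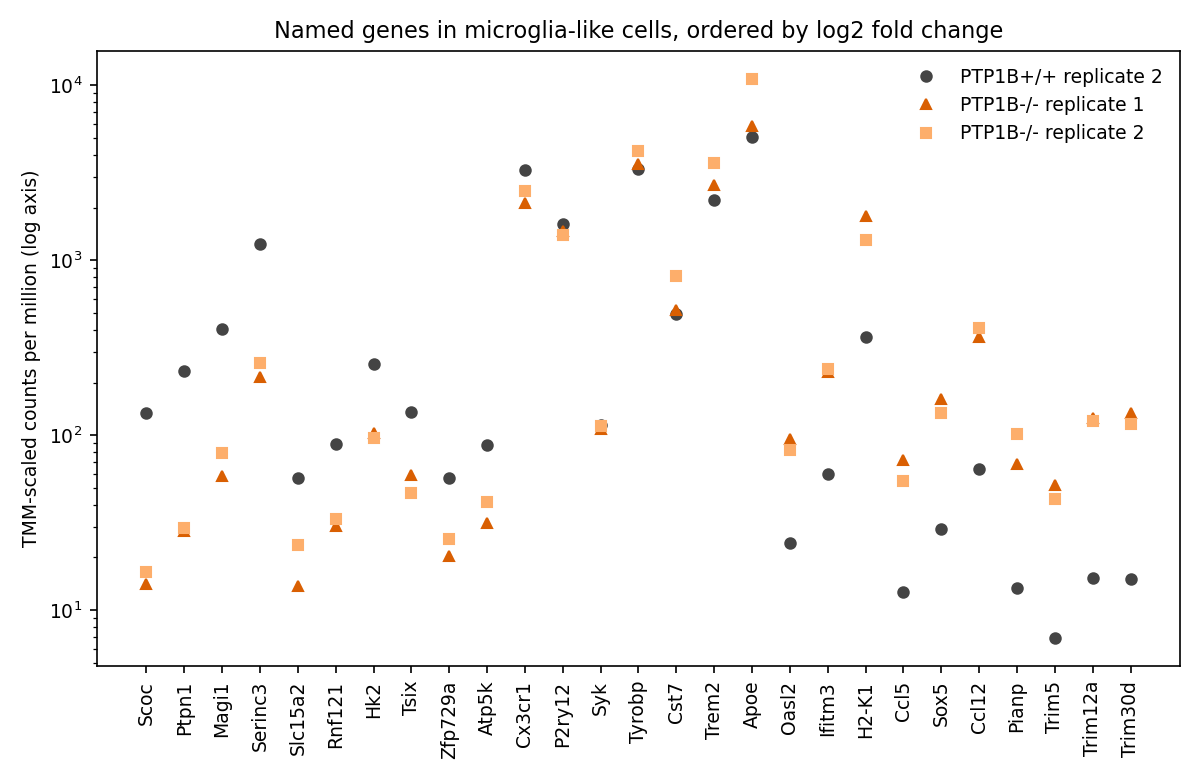
TMM-scaled CPM (y axis, log scale) of named genes in microglia-like cells, 1 point per library, genes ordered by log2 fold change along the x axis. Scoc, Ptpn1 and Serinc3 lie lower in both PTP1B-/- libraries, Trim30d, Trim12a and Ccl12 higher, and Syk lies within 108 to 115 CPM in all 3.

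Of the genes of SYK signalling, Syk, Trem2 and Tyrobp were not called in the planned fit. Syk, the kinase downstream of immune receptors, was at 115 CPM in PTP1B+/+ and 108 and 113 CPM in PTP1B-/- microglia-like cells (log2 fold change -0.06, SE 0.12, unadjusted p = 0.645, adjusted p = 0.860). Trem2, a receptor for lipids and apolipoproteins, measured 2198 CPM against 2702 and 3611 CPM (0.52, SE 0.18, adjusted p = 0.127), and its adaptor Tyrobp 3306 CPM against 3560 and 4195 CPM (0.23, adjusted p = 0.464). Microglia Trem2 was called with the older quasi-likelihood fit (adjusted p = 0.0106) and without genes of other cell types (0.0491). With thinned cells and without cluster 11 the direction turned for microglia Tyrobp (-0.0578 and -0.16) and microglia Syk (0.19 and 0.23). Of the SYK signalling list 0 of 23 members rose and 0 fell, over all genes and adjusted over the list alone (camera adjusted p = 0.272; 0.664 as an adjusted p with an estimated correlation), and its most abundant members were Tyrobp and Trem2. The PI3K, AKT and mTOR list (0 rose, 0 fell, 29 not called; adjusted p = 0.748, and 0.887 with an estimated correlation) included Inpp5d at -0.09. The list of receptor pathways that PTP1B is known to dephosphorylate (0, 0 and 17; adjusted p = 0.655, and 0.827 with an estimated correlation) included Csf1r at -0.15 and Grb2 at 0.07. Transcript levels do not measure phosphorylation. The simulated recovery of 19.4% at 1.5-fold is an average over genes of all levels, so many changes of that size would be missed. It does not describe each gene: Ppt1 (-0.42) and Npc1 (-0.44), with an SE of 0.12 like that of Syk, were called at smaller changes.

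Of the phagocytosis list 4 members rose, 0 fell and 32 were not called (4 rose adjusted over the list alone). They were Axl (1.07, SE 0.13), a receptor for phosphatidylserine bridged by Gas6, the Fc gamma receptors Fcgr1 (0.70, SE 0.12) and Fcgr4, and Arpc3, a subunit of the actin-nucleating Arp2/3 complex. The list's median was 0.13, with 0.0732 and 0.18 in PTP1B-/- replicates 1 and 2 (camera adjusted p = 0.0115; 0.664 as an adjusted p with an estimated correlation). That call ended with thinned cells (adjusted p = 0.107), without cluster 11 (0.0928) and with the shallow unnamed cluster added (0.0612). In the same sums choroid plexus markers had a median of -4.51 and oligodendrocyte markers 0.76, and the median share of mitochondrial UMIs was 1.18%, 2.25% and 1.77%, so RNA of other cells and cell quality differ beside this list.

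Of the genes of disease-associated microglia, the state described around amyloid plaques, 6 rose, 0 fell and 28 were not called, and also 6 and 0 adjusted over the list alone. Axl, Cox6a2 (1.03), Cd52, Ctsl (0.88), Csf1 and Lpl (0.73), the lipoprotein lipase, were the 6 (median 0.29, with 0.14 and 0.53 in PTP1B-/- replicates 1 and 2; adjusted p = 2.10e-06; 0.664 as an adjusted p with an estimated correlation). Apoe, the main brain apolipoprotein, stood at 5064 CPM against 5888 and 10917 CPM (0.73, SE 0.60, adjusted p = 0.674), and Cst7 at 495 CPM against 518 and 818 CPM (0.43, adjusted p = 0.679; microglia Cst7 was at -0.0139 thinned and -0.0291 without cluster 11). Without cluster 11, 0 members rose (adjusted p = 0.990), and with thinned cells 1 rose (0.119). The shifts in choroid plexus markers (-4.51), oligodendrocyte markers (0.76) and mitochondrial share stand beside this list too. Of the homeostatic list 1 of 20 members fell, 0 rose (0 and 0 adjusted over the list alone; adjusted p = 0.154, and 0.664 with an estimated correlation): Cx3cr1, the fractalkine receptor, at 3288 CPM against 2131 and 2481 CPM (-0.51, SE 0.15, adjusted p = 0.0454). P2ry12, the ADP receptor, was at -0.16 (SE 0.13, adjusted p = 0.562; microglia P2ry12 was at 0.0116 without cluster 11).

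Interferon-induced genes formed the group with the most calls in microglia-like cells. Of 33 members 23 rose, 0 fell and 10 were not called, and 27 rose and 1 fell adjusted over the list alone. Ifi44 (3.95, SE 0.25; 2.98 CPM against 52.8 and 38.5 CPM), Cxcl10 (2.22), Ifitm3 and Oasl2 were among them, and so were Irf7, Isg15, Zbp1 and Bst2. The median was 0.92, with 1.02 in PTP1B-/- replicate 1 and 0.82 in replicate 2 against the PTP1B+/+ library (camera adjusted p = 1.95e-49; 0.664 as an adjusted p with an estimated correlation). With thinned cells 11 members rose and without cluster 11 it was 10, and without genes of other cell types 4 antigen presentation members rose. Of the antigen presentation list 11 rose, 0 fell and 7 were not called (12 and 0 adjusted over the list alone; median 1.48; adjusted p = 1.38e-32, and 0.664 with an estimated correlation): the class I genes H2-K1, H2-D1 (1.72; 787 CPM against 2808 and 2377 CPM), H2-T23 (1.44) and H2-Q7, the peptide transporter genes Tap1 and Tap2, the immunoproteasome genes Psmb8 and Psmb9, the regulator Nlrc5, and the class II loading genes H2-DMa and H2-DMb1. Beside both groups, choroid plexus markers in the same sums had a median of -4.51 (5 of 9 fell), oligodendrocyte markers a median of 0.76 (4 of 10 rose) and T cell markers a median of -1.31 (0 of 4 called).

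**Figure D4:**
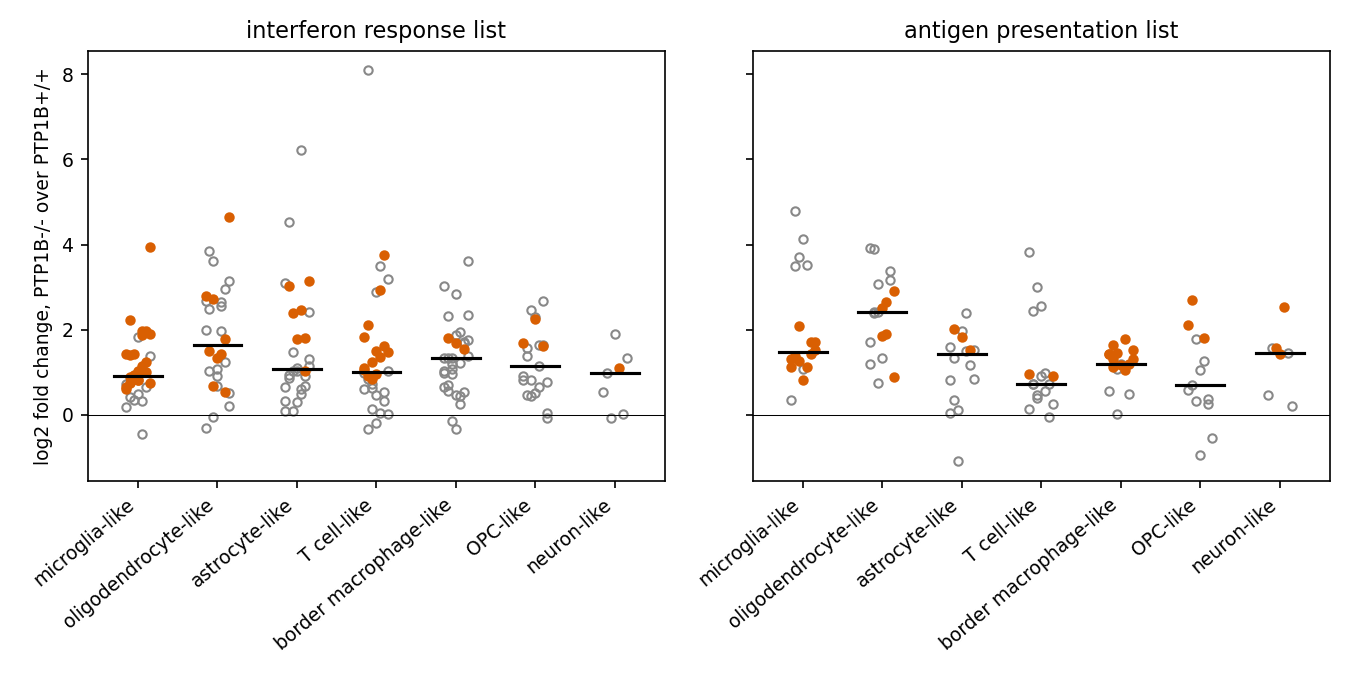
Log2 fold change, PTP1B-/- over PTP1B+/+ (y axis), of each member of the interferon response list (left) and antigen presentation list (right) in 7 cell classes (x axis). Filled points passed the test, open points did not, and horizontal lines are medians; microglia-like medians are 0.92 and 1.48.

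In the complement list C3 had the largest rise (1.88, SE 0.36), at a low 1.92 CPM against 7.87 and 5.75 CPM. C1qb (1.63, SE 0.17; 2341 CPM against 6852 and 7595 CPM) and C1qc (1.23, SE 0.16), chains of the C1q recognition molecule, rose with C1qa (0.66), 0 members fell and 7 of 11 were not called (5 rose and 1 fell adjusted over the list alone). The list's median was -0.03 while its mean was 0.62 and camera called it upward (adjusted p = 0.000222; 0.664 as an adjusted p with an estimated correlation). In the inflammatory NF-kB list Ccl5 and Bcl2a1b (0.88) rose, 0 fell and 20 were not called (4 and 0 adjusted over the list alone; adjusted p = 0.00221, and 0.664 with an estimated correlation). Of the Alzheimer's disease risk genes Sorl1 (1.79, SE 0.17), a sorting receptor, and Ctsh (0.85) rose, Clu (-1.16, SE 0.20), the apolipoprotein clusterin, fell, a fall of 13.8 raw CPM where choroid plexus RNA would bring 31.6 CPM, and 21 were not called (adjusted p = 0.177, and 0.664 with an estimated correlation; 2 rose and 1 fell adjusted over the list alone). That 31.6 CPM is more than the 24.5 raw CPM of Clu measured in the PTP1B+/+ sum, so the estimate is too high for Clu. Choroid plexus markers moved beside these groups as given above.

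In the lysosomal list Ctsh, Ctsl and Ctsc rose, Npc1 (-0.44), the cholesterol exporter, and Ppt1 (-0.42) fell, and 34 were not called (5 and 2 adjusted over the list alone; adjusted p = 0.0920, and 0.804 with an estimated correlation). In glycolysis Hk2 fell and 18 were not called (0 and 2 over the list alone; adjusted p = 0.696), and in lipid and cholesterol metabolism Lpl rose, Npc1 fell and 35 were not called (1 and 1; 0.655). Of the oxidative phosphorylation genes 2 rose, 4 fell and 77 were not called (2 and 4; 0.171), of mitochondrially encoded transcripts 5 rose and 3 fell of 13 (6 and 3; 0.655), and of ribosomal protein genes 2 rose and 6 fell of 78 (2 and 7; 0.929), the 3 bracketed values being those adjusted over the list alone and the camera adjusted p. All 4 oxidative phosphorylation genes that fell (Cox8b, Atp5k, Ndufa3 and Atp5md) and all 3 mitochondrial ones (mt-Atp8, mt-Nd6 and mt-Nd5) are at least 4 times higher in choroid plexus-like than in microglia-like cells. The share of choroid plexus RNA read from Ttr, 1.56% of the PTP1B+/+ sum, covers the whole fall of Cox8b. It covers only 36.6% of the fall of Atp5md, 22.3% for Atp5k, 17.1% for Ndufa3, and 8.55%, 11.2% and 29.1% for mt-Atp8, mt-Nd6 and mt-Nd5. In that sum all 8 choroid plexus markers compared lay below their ratio to Ttr in choroid plexus-like cells (median log2 deviation -0.67). This share can therefore be too high. Proliferation (18 members; adjusted p = 0.878) and immediate early genes (20; 0.171) had 0 called members, adjusted over the list alone as well. Among chromosome 2 neighbours of Ptpn1, Prex1 (1.06, SE 0.15) rose, Atp9a (-1.61, SE 0.29) fell and 24 were not called (1 and 1 adjusted over the list alone; 0.929). None of these lists was called with an estimated correlation either.

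Lists of other cell types also moved in microglia-like sums. Myelin genes (4 rose, 0 fell, 8 not called; 9 and 0 adjusted over the list alone; adjusted p = 3.96e-08, and 0.664 with an estimated correlation) included Mal (1.39) and Cldn11 (1.64), which measured 7.47 CPM against 23.5 and 23 CPM. The disease-associated oligodendrocyte list (5, 0 and 7; 7 and 1 adjusted over the list alone; 7.87e-13, and 0.664 with an estimated correlation) shares H2-D1 and H2-K1 with antigen presentation. The reactive astrocyte list (2, 0 and 9; 3 and 1; 0.000386, and 0.664) and the blood-brain barrier list (1, 2 and 8; 1 and 2; 0.988, and 0.995) are given in the same order. Ttr, encoding transthyretin, had at least 1 UMI in 2755 of 2755 PTP1B+/+ microglia-like cells (100%, 99.9 to 100), against 23.9% and 19.9% in PTP1B-/-, at median depths of 8767, 6632 and 6260 UMIs per cell. At 3588 CPM against 46.5 and 263 CPM, its log2 fold change of -4.51 was not called (adjusted p = 0.527), and 1017 of the 1213 UMIs in PTP1B-/- replicate 2 came from a single cell.

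Within microglial states, the planned clustering gave 30.6%, 39.4% and 52.1% disease-associated-like, 39.7%, 0.201% and 0.421% homeostatic-like, and 1.60%, 20.3% and 4.63% interferon-like cells. It split cells by library: of the disease-associated-like cells 823, 230 and 104 lay in 1 state cluster and 19, 359 and 267 in another, so its sizes and tests compare unlike cells. Another of its clusters held 4, 571 and 284 cells and was left in no named state. Against other microglia-like cells that cluster had a median log2 level of 0.277 on the homeostatic list and -1.37 on the disease-associated list. The planned homeostatic-like shares leave these cells out, so they do not show a loss of that state. In the disease-associated-like cells of the planned clustering 5621 of 11250 genes were called. There 9 interferon members rose and 7 fell of 32 (median 0.14), 7 antigen presentation members rose and 1 fell of 18, and 2 disease-associated members rose and 16 fell of 34 (median -0.67). SYK signalling had 12 rises and 4 falls of 22, and phagocytosis 7 and 11 of 34. Clustered without called genes and genes of other cell types, a setting chosen after the data were seen, disease-associated-like cells made up 54.6%, 44.4% and 54.9% of microglia-like cells, homeostatic-like cells 22.3%, 17.3% and 11.2%, and interferon-like cells 0.762%, 2.28% and 0.421%. The called genes left out include 23 of 33 interferon members, so the small interferon-like share is partly built in. Cells in no named state were 22.3%, 36.1% and 33.4%, mostly a cluster of 614, 427 and 238 cells. Against other microglia-like cells its median log2 level was 0.453 on the homeostatic list, under the naming cutoff, and -1.24 on the disease-associated list. The lower homeostatic-like share in PTP1B-/- therefore depends on that cutoff. In disease-associated-like cells of that clustering 200 genes were higher and 185 lower in PTP1B-/-, and 14 of 33 interferon and 11 of 18 antigen presentation members rose with 0 falling, as did 2 of 34 disease-associated and 0 of 22 SYK signalling members. In homeostatic-like cells 197 genes were higher and 145 lower, and 23 of 32 interferon and 8 of 18 antigen presentation members rose with 0 falling. Both states are parts of the same cells and libraries in which the genes left out of the clustering had been called. Clusters blind to those genes mix the genotypes. These rises inside states are therefore partly built in and add no separate evidence.

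Oligodendrocyte-like cells had 808 genes higher and 1128 lower of 14305 tested. Spock1, a secreted proteoglycan, rose from 1.27 CPM to 439 and 488 CPM (8.50, SE 0.16), while its raw level in astrocyte-like cells was 1.09, 3.43 and 6.10 CPM. Median depths of the oligodendrocyte-like cells were 14143, 8237 and 7288 UMIs. Cntn4 (4.38, SE 0.11), a neural adhesion molecule, Thsd4 (3.63, SE 0.13), Dscaml1 (1.74, SE 0.09) and C1qb (1.69, SE 0.13) also rose. Of interferon genes 9 rose, 0 fell and 19 were not called (11 and 0 adjusted over the list alone; adjusted p = 7.61e-08, and 0.949 with an estimated correlation), and of antigen presentation genes 6, 0 and 12 (8 and 0; 1.58e-07, and 0.949), beside microglia markers of which 7 of 19 rose (median 0.80) and choroid plexus markers of which 6 of 9 fell. The class differs in makeup: cluster 3 held 310, 547 and 449 of its 1529, 1850 and 1464 cells, and cluster 28, led by interferon genes, 1, 44 and 38, so these rises can rest on more such cells, which was not tested. Oxidative phosphorylation had 29 rises and 5 falls of 83 (42 and 5; 1.47e-05, and 0.930). Hba-a1, Hba-a2, Hbb-bs and Hbb-bt, globin genes in pairs of similar sequence, fell by 9.07 to 9.84 on the log2 scale and Ttr fell as well, but 7451 of 13443 Hbb-bs UMIs lay in a single PTP1B+/+ cell.

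Astrocyte-like cells had 89 genes higher and 348 lower of 13701 tested. Apod, a lipid carrier (2.23, SE 0.27), Trim12a (2.17), C1qb (1.79), Slc25a21 (1.78) and C1qc (1.75) were the largest rises above a mean log2 CPM of 5. Sostdc1 (-9.52), Ttr (-8.03), Ecrg4 (-5.60) and Enpp2 (-3.86) were among the largest falls, and all 9 choroid plexus markers tested fell. Ribosomal protein genes fell in 24 of 77 cases and rose in 0 (0 and 69 adjusted over the list alone; adjusted p = 7.03e-49, and 0.811 with an estimated correlation), among them Rps29 (-2.41) and Rps28 (-2.24), with medians of -0.56 and -0.94 in PTP1B-/- replicates 1 and 2. Of oxidative phosphorylation genes 0 rose and 12 fell of 84 (0 and 32; 1.25e-22, and 0.811), opposite to oligodendrocyte-like cells. Cluster 16, astrocyte-like cells led by Aldoc and Mt2, held 87, 17 and 6 cells, so the class differs in makeup between libraries. Interferon genes rose in 7 of 28 cases (12 and 0; 2.54e-14, and 0.811), with Ifit1 at 3.02, and microglia markers rose in 2 of 19 (11 adjusted over the list alone; median 1.22, all 19 positive, adjusted p = 5.80e-12, and 0.811 with an estimated correlation), so the C1q rises can be microglial RNA. Oligodendrocyte markers were higher there too (2 of 10 rose, median 1.32, adjusted p = 1.86e-07, and 0.811 with an estimated correlation). DESeq2 called 91 genes in place of 437, all but 2 of them shared, and without a filter on low counts 1 gene was higher and 51 lower.

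T cell-like cells had 108 genes higher and 123 lower of 10799. Ifitm3 (3.76, SE 0.34; 5.84 CPM against 92.5 and 67.8 CPM), Mgll, the monoacylglycerol lipase (3.19, SE 0.31), Ms4a4c (3.07), Trim12a (2.64) and Trim30d (2.55) rose most above a mean log2 CPM of 5. Ttr (-7.34), Ecrg4 (-5.76), Ptpn1 (-3.10) and Serinc3 (-2.38) were among the largest falls, and 7 of 9 choroid plexus markers fell. Of interferon genes 14 rose, 0 fell and 18 were not called (24 and 0 adjusted over the list alone; adjusted p = 1.08e-32, and 0.760 with an estimated correlation), with Isg15 at 1.83. Beside them NK cell markers (3 of 8 rose, median 0.87, adjusted p = 0.00152) and monocyte markers (2 of 5, 0.53, 0.0171) were higher, neither called with an estimated correlation (0.760 for both), so the makeup of this class may differ too. DESeq2 had 54 genes higher and 27 lower there, against more lower than higher in the planned fit. In border macrophage-like cells 98 genes were higher and 128 lower of 9291: Klrk1 (3.01), Trim12a (2.31), Dnm3 (2.24), Ms4a4c (2.23) and Ccl12 (2.19) rose most above the same level, as did 12 of 17 antigen presentation genes with 0 falling (14 and 0; 6.00e-16, and 0.737), including the class II genes Cd74 (1.13) and H2-Eb1 (1.31). The class joins clusters 17 and 20; cluster 20, with H2-Eb1, H2-Aa and H2-Ab1 among its leading genes, held 156 of 250, 104 of 143 and 111 of 140 cells, a larger part in both PTP1B-/- libraries. The neutrophil genes S100a8, Ngp, Retnlg and S100a9 were among the largest falls, with 5276 S100a8 UMIs in the PTP1B+/+ library and 0 in both others; 8 of 9 neutrophil and 4 of 9 B cell markers fell, so RNA of other blood cells was present in the PTP1B+/+ sum, and the cause was not tested. Without a filter on low counts 1 gene was higher and 22 lower there, and with DESeq2 107 were higher and 24 lower, so the balance of directions depends on the method.

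OPC-like cells had 103 genes higher and 164 lower of 12541. Snhg11 (3.73, SE 0.30), Trnp1 (2.93), Prom1 (2.60) and the mitotic genes Ube2c (2.55) and Cenpf (2.14) rose most above a mean log2 CPM of 5, and 5 of 22 proliferation genes rose with 0 falling (10 and 0 adjusted over the list alone; adjusted p = 4.67e-06, and 0.813 with an estimated correlation). The proliferation median was 0.88 in PTP1B-/- replicate 1 and 0.26 in replicate 2, and the dividing cells of cluster 25, led by Top2a and Ube2c, numbered 3, 8 and 2, so few cells can carry these rises. Oligodendrocyte markers were higher in the same sums (2 of 10 rose, median 0.93, all 10 positive, adjusted p = 5.42e-07, and 0.813 with an estimated correlation). Neuron markers had medians of 0.30 and 0.20 in PTP1B-/- replicates 1 and 2, with 4 of 7 higher in both. Snhg11 is among the 10 leading genes of neuron-like cluster 8, and whether neuronal RNA carries its rise was not tested. Inpp4b, a phosphoinositide phosphatase, fell (-2.43, SE 0.18), as did Chchd10 (-2.95), Sostdc1 (-7.86), Ttr (-7.86), Ecrg4 (-5.41) and all 8 choroid plexus markers tested; choroid plexus RNA, 4.00% of that sum by Ttr, covers 89.1% of the fall of Chchd10 and 0.323% of that of Inpp4b. Neuron-like cells, the smallest class tested (298, 74 and 120 cells), had 115 genes higher and 229 lower of 9197. Rreb1 (2.10), Adcy2 (1.88), Gdf5 (1.69), Slc24a3 (1.63) and H2-D1 (1.58) rose most within the limits given for microglia-like cells, and Ecrg4, Kl, Prlr, Ptpn1 and Calml4, at 0 UMIs in both PTP1B-/- libraries against 379, 198, 196, 141 and 153, fell most. In the neuron-like PTP1B+/+ sum choroid plexus RNA, 5.48% by Ttr, covers the whole fall of Ecrg4 and of Calml4. It covers 91.7% of the fall of Prlr and 73.7% of that of Kl, but 4.41% of that of Ptpn1. DESeq2 called 53 genes in OPC-like and 32 in neuron-like cells.

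Across the 7 classes, which share the same 3 libraries, 34 genes were higher and 115 lower in at least 4 classes, of 11817 tested in at least 4. Of the 115 lower genes 64 were at least 4 times higher in choroid plexus-like than in microglia-like cells, against 9.89% of the 11817. C1qb was called in 6 of 7 classes, from 1.08 in border macrophage-like to 1.79 in astrocyte-like cells, and H2-D1 in 5 of 7, from 1.20 in border macrophage-like to 1.80 in OPC-like cells.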

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

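Several genes differed between genotypes by another amount in microglia-like cells than in a second cell class, tested with the planned genotype-by-class interaction. For each named gene the class with the clearest difference is given, a choice made from the results. Values are the log2 fold change in microglia-like cells minus that in the other class. Ptpn1 fell less in microglia-like than in oligodendrocyte-like cells (4.94, adjusted p = 1.69e-15), where only 3 and 1 UMIs remained. Scoc fell in both microglia-like and oligodendrocyte-like cells, and more in the former (-2.53, 1.86e-23). Magi1 fell in microglia-like cells and rose in neuron-like cells (0.87 there; difference -3.49, 7.87e-47). Serinc3 (0.66 in OPC-like cells; -3.11, 5.95e-39), Rnf121 (-0.27 in oligodendrocyte-like cells; -1.26, 7.23e-07), Hk2 (0.44 in oligodendrocyte-like cells; -1.79, 0.0217) and Slc15a2 (-0.03 in astrocyte-like cells; -1.71, 6.94e-06) fell in microglia-like cells and were not called in the other class. So did Cx3cr1 (0.91 in astrocyte-like cells; -1.47, 0.0235), but microglia markers as a list were higher in the astrocyte-like sums (median 1.22), so microglial RNA there bears on this difference. Sox5 (0.01 in OPC-like cells; 2.29, 4.05e-31), Pianp (0.26 in neuron-like cells; 2.37, 5.86e-10), Ccl5 (-0.10 in oligodendrocyte-like cells; 2.43, 3.17e-06) and Trim30d (1.75 in border macrophage-like cells; 1.32, 0.0330) rose in microglia-like cells and were not called in the other class. Apoe (1.38 against neuron-like cells, 0.000609) and Cst7 (0.78 against oligodendrocyte-like cells, 0.0485) had the higher value in microglia-like cells, though neither was called there alone. In neuron-like sums Apoe fell from 347 to 217 and 214 raw CPM. Choroid plexus RNA would bring 178 CPM to that PTP1B+/+ sum, which covers the whole fall and so bears on the Apoe difference. Ifitm3 rose less than in T cell-like cells (-1.85, 0.00128). H2-K1 had a lower value than in oligodendrocyte-like cells (-0.94, 0.0122), where its own change was not called (3.08, SE 0.97).

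Over all genes, 498 of 15855 differed from oligodendrocyte-like, 305 of 15126 from astrocyte-like, 279 of 14767 from OPC-like, 158 of 14672 from neuron-like, 125 of 13339 from T cell-like and 110 of 13185 from border macrophage-like cells.

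The free RNA test of choroid plexus transcripts was set before its result was seen, and the other tests named here were chosen afterwards. Choroid plexus transcripts such as Ttr were lower in PTP1B-/- cells of every tested class. In the PTP1B+/+ library their ratios to Ttr lay near those inside choroid plexus-like cells, with a median log2 deviation of 0.0153 and 52 of 56 ratios within 1, which is consistent with free RNA from the 5011 choroid plexus-like cells. By class the medians ran from -0.87 in oligodendrocyte-like and -0.67 in microglia-like cells, where all 8 markers lay below 0, to 0.47 in border macrophage-like cells, and the cause of these departures was not tested. Doublets alone would leave many cells without Ttr, but 100% of the PTP1B+/+ microglia-like cells carried it. Where free RNA reaches every cell, that does not exclude doublets as well. Unnamed cluster 1, with markers of both microglia and choroid plexus, held 101 PTP1B+/+ cells and 0 PTP1B-/- cells. A change in Ttr transcription was looked at in choroid plexus-like cells only, where Ttr was 1.36 times as high or more in PTP1B-/-. That value does not measure transcription in the other classes, and Ttr is among the markers that named the class. The test therefore cannot exclude such a change.

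Interferon and antigen presentation genes such as Ifi44 and H2-K1 rose in PTP1B-/- microglia-like cells. Leaving out cluster 21, the interferon-rich one (36, 115 and 18 cells of PTP1B+/+ replicate 2 and PTP1B-/- replicates 1 and 2), left 22 interferon members risen. The planned state clustering put 44, 304 and 33 cells in the interferon-like state, so most such cells of PTP1B-/- replicate 1 stayed in the sums. Whether more cells of that kind are the source is therefore not decided by this test. T cell markers allow at most 0.790% of T cell RNA in the PTP1B-/- sums, while the risen members would need a median of 35.0% and 29.7%, which argues against T cell RNA as the source. A property of the lone PTP1B+/+ library could not be excluded. The test written for it, camera with an estimated correlation (adjusted p = 0.664), rests on 1 residual degree of freedom and cannot decide the question. Both PTP1B-/- libraries lay above the PTP1B+/+ library, the lower at a median of 0.82. That does not separate PTP1B deficiency from a property of the lone library.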

How the results depend on the processing

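Of 916 genes called in microglia-like cells, the count became 520 without a filter on low counts, 1432 with the older quasi-likelihood fit, 329 with DESeq2, 210 with thinned cells and 358 without cluster 11. In OPC-like cells (267) it was 516 without the filter and 53 with DESeq2, in T cell-like cells (231) 374 with the older fit and 81 with DESeq2, and in astrocyte-like cells (437) 52, 789 and 91 for no filter, older fit and DESeq2. In border macrophage-like cells (226) it was 135 with RLE size factors, 23 without the filter, 345 with the older fit and 131 with DESeq2, in neuron-like cells (344) 32 and in oligodendrocyte-like cells (1936) 537 with DESeq2. With an estimated correlation 0 lists were called in each of the 7 classes, fry's directional test called 0 in microglia-like cells and 2 in OPC-like cells (the receptor list linked to PTP1B downward, adjusted p = 0.0344, and neuron markers upward, 0.00723), and thinning left 8 of 16. The test with an estimated correlation rests on 1 residual degree of freedom and could hardly call any list, so its lack of calls decides nothing. In microglia Tyrobp turned to -0.0578 thinned and -0.16 without cluster 11, microglia Syk to 0.19 and 0.23, microglia Cst7 to -0.0139 and -0.0291, and microglia P2ry12 to 0.0116 without cluster 11. Without choroid plexus-like cells the log2 ratios of shares were -0.96 for microglia-like, 0.32 for T cell-like, 0.56 for oligodendrocyte-like and 0.74 for astrocyte-like cells. At resolution 0.5 oligodendrocyte-like cells had 1.52 and astrocyte-like cells 1.77, and with all barcodes oligodendrocyte-like cells had 1.44. The 1.52 leaves out an unnamed cluster of 721, 852 and 462 cells with 10 oligodendrocyte markers detected, so it depends on the naming rule. In the order PTP1B+/+ replicate 2, PTP1B-/- replicates 1 and 2, thinned cells gave disease-associated-like shares of 27.7%, 27.9% and 41.0%, beside 22.8%, 12.2% and 12.1% in a proliferating-like state whose main cluster also carries disease-associated genes (counted together, PTP1B-/- replicate 1 lies below PTP1B+/+), homeostatic-like 46.6%, 2.84% and 2.72%, and interferon-like 0.922%, 15.0% and 2.57%. At resolution 1 disease-associated-like cells were 51.8%, 39.0% and 53.4%, so PTP1B-/- replicate 1 turned from above to below PTP1B+/+, which had 24.6% homeostatic-like cells, and PTP1B-/- replicate 1 had 10.3% interferon-like cells. The clustering without called genes and genes of other cell types gave 54.6% and 44.4% disease-associated-like in the first 2 libraries. It gave 22.3%, 17.3% and 11.2% homeostatic-like, and 0.762%, 2.28% and 0.421% interferon-like, with 385 genes called in disease-associated-like cells. With thinned cells 2.04%, 42.0% and 41.6% were in no named state, in a cluster above 0 on the homeostatic list (0.312). Clusters above 0 on that list also stayed unnamed in the other clusterings. The homeostatic-like shares therefore depend on the naming cutoff and do not show a loss of that state. Leaving out 1 PTP1B-/- library leaves 1 against 1 with no test for counts; over these the complement median ran from -0.101 to 0.0509 and the microglia-like share ratio from -0.49 to 0.12. No paired analysis was possible because the groups share just 1 replicate number among the analysed libraries. Settings added after the data were seen were leaving out clusters, adding the shallow unnamed cluster, leaving out choroid plexus-like cells, the clustering without called genes, the estimated correlation outside microglia-like cells, and leaving out libraries for shares and Ptpn1. A block for replicate number, planned for the case of both PTP1B+/+ libraries, was not run.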

Other observations

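The genes in these paragraphs were chosen after their values were seen. Across the 7 cell classes some ribosomal protein and respiratory chain genes moved together in the PTP1B-/- libraries, in both directions. Rps29 was called in 7 of 7 classes (median log2 fold change -1.91, range -2.41 to -1.28), Atp5k in 7 of 7 (-1.47), Rps28 in 6 (-1.43) and Rpl38 in 6 (-1.29), all lower, while Rpl21 rose in 5 (0.60). Among mitochondrial transcripts mt-Atp8 fell in 4 classes (-2.34) while mt-Atp6 rose in 7 (1.01), mt-Co3 in 6 (1.21) and mt-Co1 in 6 (0.76). Atp5k and mt-Atp8 are at least 4 times higher in choroid plexus-like than in microglia-like cells, but the choroid plexus RNA read from Ttr covers only 22.3% and 8.55% of their falls in microglia-like sums. Over the classes its part of the Atp5k fall ran from 9.61% in oligodendrocyte-like to 52.0% in border macrophage-like sums. For mt-Atp8 it was 28.2% in OPC-like and 42.7% in neuron-like sums. The median share of mitochondrial UMIs was higher in both PTP1B-/- libraries in all 7 classes (microglia-like 1.18%, 2.25% and 1.77%, oligodendrocyte-like 1.83%, 4.14% and 3.99%), and 5.38%, 11.5% and 11.3% of barcodes failed the filters, so cell quality differs with the group. All classes share the same 3 libraries, so such shifts can come from library preparation, and the cause was not tested.

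Cntn4, an adhesion molecule, stood at 20.1 raw CPM in PTP1B+/+ oligodendrocyte-like cells against 434 and 420 CPM in PTP1B-/-. In cluster 28, oligodendrocyte-like cells with interferon genes, there were 1, 44 and 38 cells of PTP1B+/+ replicate 2 and PTP1B-/- replicates 1 and 2.

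The test around Ptpn1 was set before its result was seen, and the one on gene pairs afterwards. Gm47015, Eps8l1, Clcn4, Gm21860 and Gm47283 were nearly absent from PTP1B-/- cells: called lower in at least 4 classes and at least 16-fold lower by the median. Ptpn1 was left out of this list. Genes at least 4 times higher in choroid plexus-like than in microglia-like cells were left out too, such as Kl (median log2 fold change -9.32) and Clic6 (-8.11). Within 10 Mb of Ptpn1, 14 of 135 genes were called in microglia-like cells against 901 of 13854 elsewhere (odds ratio 1.66, exact interval 0.879 to 2.92, Fisher p = 0.0786). The bound written beforehand against a kept chromosome segment, a p of 0.05 or above, was met. That bound was too loose, because the interval includes 1 and values well above it, and a missed threshold does not exclude enrichment. Of those 14, 10 were lower: Lbp (-9.0), Wfdc2 (-4.44), 5031425F14Rik (-3.29), Serinc3 (-2.39), Ada (-1.95), Atp9a (-1.61), Ttpal (-1.43), Pltp (-1.16), Pkig (-0.82) and Gm20721 (-0.72). The other 4, Sdc4 (0.96), Sys1 (0.53), Prex1 (1.06) and Zbp1 (1.97), were higher. Lbp, Wfdc2, Pltp and Sdc4 are at least 4 times higher in choroid plexus-like than in microglia-like cells and were counted all the same. The nearly absent genes formed 2 pairs within 5 Mb, Eps8l1 with Clcn4 on chromosome 7 and Gm21860 with Gm47283 at the end of Y, whose reads in female mice can come from the matching end of X and so count as 1 place. The pairs were counted after the positions were seen, so they do not decide whether strain variants at other places of the genome lie behind these genes, and that stays open.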
